A study of Homo sapiens with 12 samples.

How the data were processed

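RNA was measured in MV3, an established human melanoma line derived from a lymph node metastasis. Per the labels' protocols, cells grown in medium with 10% serum were kept for 3 h in medium with 1% serum and then for 24 h in fresh medium (Ctrl) or in medium conditioned by macrophages made from the THP-1 monocyte line. The macrophages were differentiated with a phorbol ester (M0) and then, for 2 of the media, polarized with lipopolysaccharide and interferon-gamma (M1) or with interleukin 4 and interleukin 13 (M2). Each group had 3 samples, 12 in all, and groups and replicate numbers were taken from the labels. Nothing in the labels states that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Ctrl medium had not been conditioned by any cells, so each comparison with Ctrl includes conditioning itself, and carry-over of the stimulants in the media was not measured.

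Per the labels' protocols, stranded mRNA libraries were sequenced as single reads of 50 nt in 2 runs, which the deposited files do not separate. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.36, Bowtie2 2.2.3, STAR 2.5.4b, R 3.3.3 and 3.5.0, DESeq2 1.20.0 and human genome build hg38. The counting tool, its strand setting and the annotation release are not given in the sources used here. The authors deposited a table of raw read counts for 58288 gene identifiers in the 12 samples, and the per-sample count files equalled its columns in 12 of 12 cases. A second table that the authors deposited is named as variance-stabilized, and its values rise as log2 of the count at high counts. In 12 of 12 samples each value in it was an increasing function of the count, and a count of 0 had the value 3.22. The log2 values were used only in an alternative test.

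Gene symbols and coordinates came from GENCODE release 29 on GRCh38, which matched 55661 identifiers with their version and 58025 without it. Because the strand setting is not known, reads of a gene that overlaps another on the opposite strand cannot be told apart. Of the genes named most often this applies to TNFAIP3, SOD2, ICAM1, IL6, TAP1, PSMB9, TYMS, PLK1, TNC, CISH and AXL. HLA-B overlaps HLA-C in the annotation and belongs to a family of near-identical genes, so its counts are uncertain.

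Library totals ran from 21788397 to 42921242 counts. A count of 0 allows up to 3 counts, or 0.0699 to 0.138 CPM in a single library. Ratios of reads are given with exact 95% intervals where a group had 1 to 3 reads in all, and as a lower bound against 3 reads per group where it had 0. Such intervals and floors cover counting error only, since reads were not counted by molecule. Replicate pairs differed by more than sampling noise, with chi-square per degree of freedom of 3.41 to 31.18, so none was treated as a repeat deposit of another library. Replicates were taken from the labels.

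Genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test on the deposited counts of all 12 libraries in 1 fit of group means, with TMM scaling, filterByExpr (minimum count 10, minimum total 15), and Benjamini-Hochberg adjustment at 0.05. The filter left 14088 genes, and the common biological coefficient of variation was 0.0831. Comparisons were M1 against M0, M2 against M0, M1 against M2, each conditioned medium against Ctrl, and any difference among M0, M1 and M2. Log2 CPM values used a prior count of 2. Log2 fold changes came from the edgeR fit, which did not use that prior count, so folds of genes with few reads are little damped. Standard errors (SE) come from the spread of log2 CPM over 3 and 3 libraries, and so from another estimate than the fold change beside them. Levels are mean CPM ± SD with n = 3 per group.

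Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted within a comparison, and again with a correlation estimated per list. The 20 lists covered the NF-kB pathway, cytokines and chemokines, type I interferon-stimulated genes, interferon-gamma-type genes, MHC class I antigen presentation, the interleukin 4 and 13 response, melanocytic differentiation, the dedifferentiated state, matrix remodelling, adhesion molecules, cytokine receptors, cell cycle, hypoxia and glycolysis, the ATF4 amino acid response, cholesterol synthesis, the unfolded protein response, NRF2 and metallothionein genes, TGF-beta and YAP targets, MAPK output, and macrophage markers. No macrophage marker passed the filter, so 19 lists were tested. Of these, the call was kept with an estimated correlation for 4 of 12 lists in M1 against M0, 0 of 2 in M2 against M0, 5 of 11 in M1 against M2, 1 of 7 in M0 against Ctrl, 5 of 13 in M1 against Ctrl and 1 of 7 in M2 against Ctrl.

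Named genes followed a rule. It took the 5 highest and 5 lowest log2 fold changes with at least 1 CPM in the higher group and no overlap between groups, the 3 most changed members of the 5 leading lists, the most changed member of each other list, and a panel of TNF, TNFRSF1A, TNFRSF1B, NFKB1, RELA, IL6, CXCL8, CCL2, ICAM1, MITF and AXL. M1 and M2 against Ctrl used 3 and 3 genes, and 2 members of 3 lists. Groups, tests, lists, named-gene rule and most alternatives were set before the data were examined. Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom, limma-trend on the deposited log2 values, a replicate block, the 6 compared libraries alone, each library left out in turn, an estimated correlation, and fry. Protein-coding genes alone, and leaving out M0 replicate 3 with M2 replicate 2, were chosen after seeing the data. Single values of some genes that the rule or a group took in are not reported here.

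The gene test was tested on simulated data with known changes, built from the real library sizes and the means of the second group compared. Each run changed 66, 67 and 67 genes by 0.5, 1 and 2 on the log2 scale, all at 1 CPM or more. The test recovered 68.2% of genes changed by 0.5 in M1 against M0, 74.2% in M2 against M0 and 66.7% in M1 against M2. At a log2 change of 1 the shares were 97%, 97% and 95.5%. False calls, counted once per run, were 14, 8 and 13 among 13565, 13525 and 13684 genes tested. True calls at 0.5, 1 and 2 were 45, 65 and 67 in M1 against M0, and 49, 65 and 67 in M2 against M0. In M1 against M2 they were 44, 64 and 67. The real comparisons call far more genes than were changed here, so these shares may not carry over to them or to genes under 1 CPM. Against Ctrl the shares at 0.5 were 72.7% for M0, 77.3% for M1 and 68.2% for M2.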

Results

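Gene-level read counts were obtained from 12 samples of MV3 melanoma cells exposed for 24 h to fresh medium or to medium conditioned by M0, M1 or M2 macrophages, with n = 3 per group. Total counts of replicates 1, 2 and 3 were 42921242, 28706025 and 30592714 in Ctrl, 29952546, 21788397 and 29335182 in M0, 40066328, 32566105 and 37397836 in M1, and 36527984, 27938253 and 27934789 in M2. The design names the differences among the M0, M1 and M2 media as the main question, and fresh medium as the control. Adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for lists. List members named because they moved against the rest of their list were chosen after their values were seen.

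The 4 groups separated in the leading components. Component 1, with 61.1% of the variance, placed Ctrl at -78.7 to -77.6, M0 at -2.7 to 13.3, M2 at 20 to 24.7 and M1 at 48.8 to 50.8. Component 2 held 20.1%, with M1 at 34.7 to 39.5 and both other conditioned media at -32.2 to -19. Component 3 held 6.7% and parted M0 from M2, with M0 replicate 3 at -34.2 beside -14.7 and -7.9 in the other M0 libraries. Among M0, M1 and M2, 7970 of 14088 genes (56.6%) differed in the joint test.

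**Figure D1:**
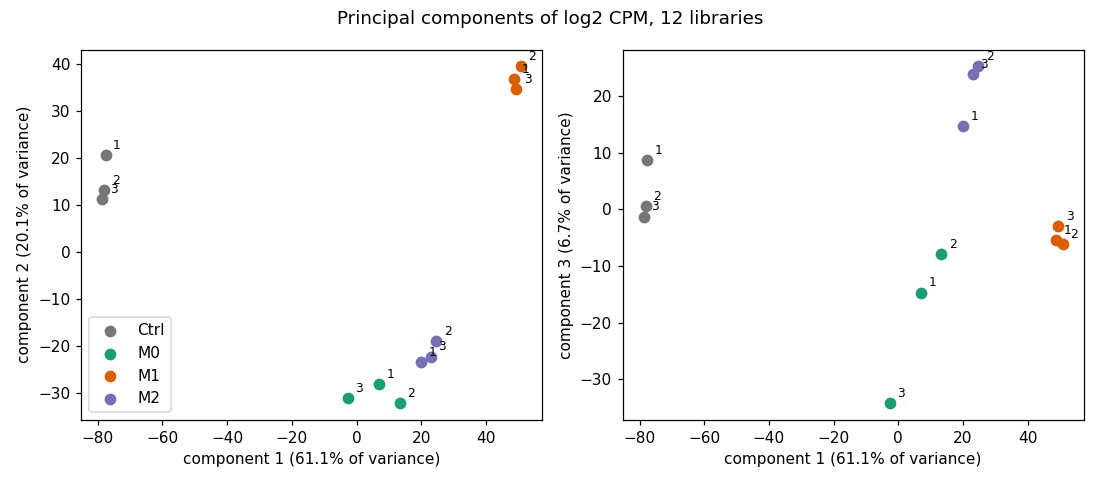
Principal components of log2 CPM in the 12 libraries, coloured by group, with component 1 (61.1% of variance) on both x axes and component 2 (20.1%) or 3 (6.7%) on the y axis. The 3 Ctrl libraries lie at -78.7 to -77.6 on component 1, and M0 replicate 3 lies lowest on component 3 at -34.2.

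Medium from M1 macrophages was compared with M0 medium to find what polarization with lipopolysaccharide and interferon-gamma changed in the melanoma cells. Interferon-stimulated genes rose. OAS2, an antiviral sensor of double-stranded RNA, stood at 267 ± 5.37 CPM in M1 and 1.28 ± 0.109 CPM in M0, a 208-fold rise (log2 7.70 ± 0.07 SE, adjusted p = 6.07e-18). IFI44L rose 222-fold, from 0.651 ± 0.172 to 148 ± 8.54 CPM (adjusted p = 2.12e-14). All 30 members of the type I interferon list rose, 30 also when adjusted over the list alone, with a median log2 fold change of 4.63, or 4.54 with the genes at or near 0 reads set at their bound (adjusted p = 8.38e-28). GBP1P1, a guanylate-binding protein pseudogene, had 129 reads in M1 and 0 in M0, at least 31.9-fold higher.

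Antigen presentation and NF-kB genes moved the same way. All 16 measured genes of MHC class I presentation rose, 16 adjusted over the list alone (median log2 1.70, adjusted p = 1.39e-14), among them the peptide transporter gene TAP1, from 18.7 ± 2.27 to 172 ± 7.87 CPM, and HLA-B, from 62.6 ± 6.49 to 629 ± 43.9 CPM. Of 23 NF-kB pathway genes 20 rose, 0 fell and 3 did not pass, with 20 and 0 adjusted over the list alone (median log2 1.04, adjusted p = 5.94e-12). TNFAIP3, a feedback inhibitor of NF-kB signalling, rose 10.7-fold to 242 ± 7.04 CPM (adjusted p = 3.41e-14), and SOD2, the mitochondrial superoxide dismutase gene, rose from 239 ± 33.2 to 2039 ± 81.7 CPM. Of 12 measured interferon-gamma-type genes 11 rose, 11 adjusted over the list alone (median log2 2.40, adjusted p = 1.01e-07). The exception was CD274, which encodes the checkpoint ligand PD-L1 and fell by 0.51 on the log2 scale (adjusted p = 0.00107).

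Inflammatory mediators and ICAM1 were higher in M1 than in M0. Of 18 measured cytokine and chemokine genes 17 rose and 1 did not pass, with 17 adjusted over the list alone (median log2 2.33, adjusted p = 2.15e-10, but adjusted p = 0.0807 with an estimated correlation). IL6 rose 5.5-fold, from 45.9 ± 5.42 to 253 ± 30.1 CPM (log2 2.46 ± 0.14 SE, adjusted p = 5.07e-11), and the chemokine gene CCL5 rose by log2 5.04 ± 0.21. CXCL8, a neutrophil chemoattractant gene, rose from 114 ± 80.6 to 970 ± 147 CPM (log2 3.08 ± 0.60 SE, adjusted p = 4.54e-06), and the log2 fold change was 3.82 without M0 replicate 3. ICAM1, a leukocyte adhesion receptor gene, rose 6.94-fold to 558 ± 19 CPM (adjusted p = 1.11e-10). IL1B, chosen after its values were seen, rose from 108 ± 10.2 to 1120 ± 95.2 CPM (log2 3.37 ± 0.11 SE, adjusted p = 2.21e-13).

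Cell cycle genes were lower in M1. Of 27 members 25 fell, 26 adjusted over the list alone (median log2 -0.85, adjusted p = 2.72e-08, but adjusted p = 0.121 with an estimated correlation). TYMS, the thymidylate synthase gene, fell from 106 ± 46.5 to 26.1 ± 4.23 CPM and the mitotic kinase gene PLK1 from 167 ± 48.1 to 49.8 ± 7.04 CPM, while the cyclin gene CCNE2 rose by log2 0.68. The M0 libraries differed in TYMS, at 96.0, 66.0 and 157 CPM in replicates 1 to 3. AXL, a receptor tyrosine kinase gene of dedifferentiated melanoma, fell by 0.76 on the log2 scale (SE 0.05, adjusted p = 4.57e-06), from 2126 ± 55.7 to 1254 ± 66.8 CPM.

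A further 6 lists passed in M1 against M0 with the preset correlation and not with an estimated one. Cytokine receptor genes had 13 of 19 up and 2 down, 13 and 2 adjusted over the list alone (adjusted p = 0.000485, and adjusted p = 0.121 with an estimated correlation), with IFNAR2, an interferon receptor subunit gene, at log2 1.65. Unfolded protein response genes had 11 of 14 up and 1 down, XBP1, and 12 and 1 adjusted over the list alone (adjusted p = 0.000563, and adjusted p = 0.195 with an estimated correlation). Adhesion genes had 10 of 15 up and 1 down, ITGA6, and 10 and 3 adjusted over the list alone (adjusted p = 0.00274, and adjusted p = 0.309 with an estimated correlation). Matrix genes had 10 of 15 up and 2 down, TIMP1 and MMP3, and 11 and 2 adjusted over the list alone (adjusted p = 0.00704, and adjusted p = 0.31 with an estimated correlation). Of 7 measured interleukin 4 and 13 response genes 3 rose, 3 adjusted over the list alone, led by the transglutaminase gene TGM2 at log2 1.87 ± 0.13 SE (adjusted p = 0.045, and adjusted p = 0.216 with an estimated correlation). MAPK output genes had 9 of 16 down and 2 up, JUNB and FOSB, with 9 and 2 adjusted over the list alone (adjusted p = 0.045, and adjusted p = 0.31 with an estimated correlation).

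The other 7 tested lists did not pass in M1 against M0. They were the dedifferentiated state (8 of 16 rose and 3 fell, adjusted p = 0.0663), the ATF4 response (3 of 18 rose and 10 fell, 0.0829), TGF-beta and YAP targets (6 of 13 rose and 3 fell, 0.422), hypoxia and glycolysis (5 of 17 rose and 9 fell, 0.601), cholesterol synthesis (7 of 19 rose and 6 fell, 0.619), melanocytic differentiation (2 of 8 rose and 3 fell, 0.624) and NRF2 (4 of 13 rose and 3 fell, 0.624). Adjusted over the list alone the counts differed only for melanocytic genes, with 2 up and 4 down. The NRF2 list had a median log2 of -0.08 and a mean of 0.19. In all, 7354 genes differed between M1 and M0, 3586 higher and 3768 lower, and 1294 of them by at least 2-fold, 843 higher and 451 lower.

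**Figure D2:**
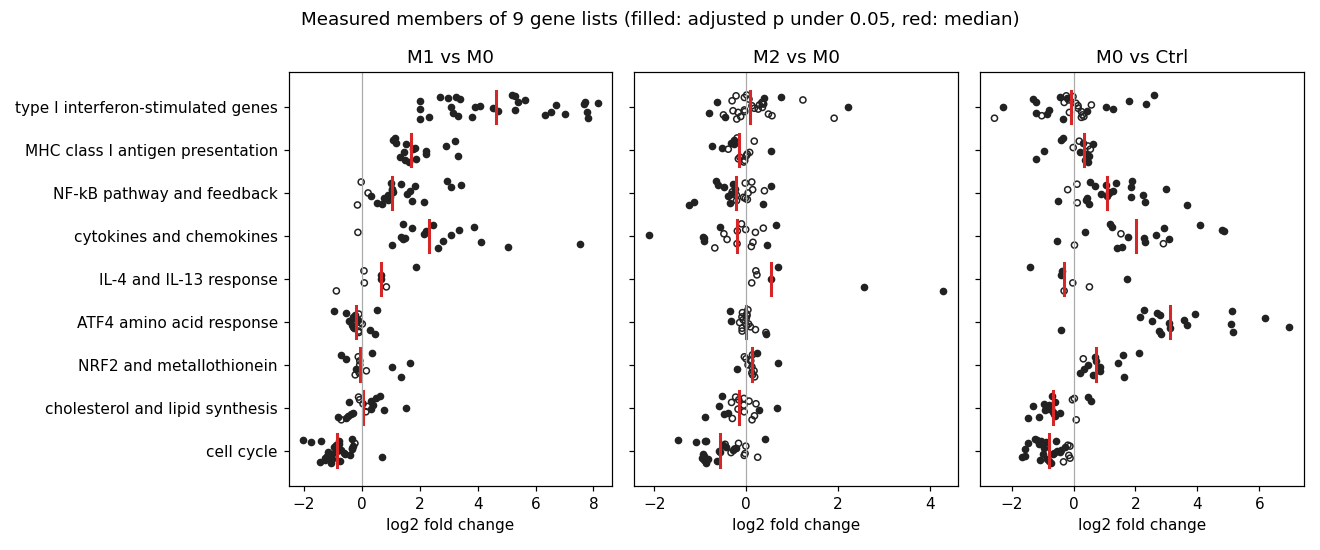
Log2 fold changes of the measured members of 9 gene lists (points) in M1 against M0, M2 against M0 and M0 against Ctrl, filled where adjusted p was under 0.05, with the list median as a red line. The type I interferon list has a median of 4.63 in M1 against M0 and 0.09 in M2 against M0, and the ATF4 list has a median of 3.10 in M0 against Ctrl.

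Medium from M2 macrophages was compared with M0 medium to find what polarization with interleukin 4 and interleukin 13 changed. TNC, which encodes the matrix glycoprotein tenascin C, rose 3.53-fold, from 189 ± 33.2 to 666 ± 78.4 CPM (log2 1.82 ± 0.18 SE, adjusted p = 5.36e-07). Of 7 measured interleukin 4 and 13 response genes 4 rose and 3 did not pass, with 6 adjusted over the list alone (median log2 0.53, adjusted p = 0.000387, but adjusted p = 0.198 with an estimated correlation). Among them were CCL26, the eotaxin-3 gene, with 76 reads in M2 and 3 in M0, a ratio of 21.7 (95% counting interval 7.15 to 108), and CISH, a cytokine signalling inhibitor gene, from 0.165 ± 0.0521 to 0.993 ± 0.195 CPM (log2 2.57 ± 0.26 SE, adjusted p = 0.000859). TENM2 rose by log2 2.15 ± 0.24, and IL6 by 0.64 ± 0.12 (adjusted p = 0.00102), to 71.7 ± 5.17 CPM.

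Of 18 measured cytokine and chemokine genes 2 rose in M2 against M0, 5 fell and 11 did not pass, with 2 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.436). IL6 rose by 0.64 on the log2 scale, and M0 replicate 3 stood highest among the M0 libraries in CXCL8 and PTGS2. CXCL8 fell by 2.11 on the log2 scale (SE 0.63, adjusted p = 0.00132), with 87.1, 51.1 and 205 CPM in the M0 libraries and a mean of 26.4 ± 7.49 in M2. Without M0 replicate 3 the log2 fold change was -1.38. PTGS2, the inducible cyclooxygenase gene, fell by 2.12 (adjusted p = 0.00322), with 31.9, 19.2 and 91.8 CPM in the M0 libraries and a log2 fold change of -1.21 without M0 replicate 3. With M2 replicate 2 left out as well, the PTGS2 call ended (adjusted p = 0.0601). MMP3, a stromelysin gene, fell by 2.04 (SE 0.50, adjusted p = 0.000915), and BDKRB1, a bradykinin receptor gene, by 2.19 (SE 0.26, adjusted p = 0.000799). ICAM1 fell by 0.37 (adjusted p = 0.0338), a call that ended without M0 replicate 3, at log2 -0.184 (adjusted p = 0.23). It also ended without M2 replicate 1, 2 or 3 (0.086, 0.0754 and 0.0989), where log2 fold changes were -0.358, -0.393 and -0.364. Of 23 NF-kB genes 2 rose (BCL3 and TNFAIP2), 10 fell and 11 did not pass, with 2 and 11 adjusted over the list alone, and the list did not pass (adjusted p = 0.0703).

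Cell cycle genes were lower in M2 than in M0 as well. Of 27 members 18 fell, 8 did not pass, and UHRF1 rose by log2 0.40, with 18 and 1 adjusted over the list alone (median log2 -0.58, adjusted p = 1.02e-06, but adjusted p = 0.528 with an estimated correlation). TYMS fell from 106 ± 46.5 to 38.1 ± 4.72 CPM and PLK1 from 167 ± 48.1 to 78.5 ± 15.4 CPM. M0 replicate 3 had the highest TYMS of the M0 libraries, at 157 CPM beside 96.0 and 66.0. The other 17 lists did not pass, with adjusted p up to 0.797. Type I interferon genes had 3 of 30 up (IRF9, STAT2 and SAMD9L) and 3 down (IFI44, OAS3 and DDX58), 3 and 3 adjusted over the list alone (adjusted p = 0.545). IL1B, at 108 ± 6.38 CPM in M2 and 108 ± 10.2 in M0, did not pass (adjusted p = 0.953).

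The number of genes called between M2 and M0 depended on single libraries. It was 3553, 1765 higher and 1788 lower, and fell to 1595 without M0 replicate 3, 1933 without M2 replicate 2, 1905 without M2 replicate 3, and 520 without both M0 replicate 3 and M2 replicate 2. Of the 3553 genes, 516 (14.5%) were called with both left out. At least 2-fold changes numbered 313, 214 higher and 99 lower, and 133 without M0 replicate 3, 210 without M2 replicate 2, and 73 without both. TNC, CCL26, CISH, TENM2, BDKRB1 and MMP3 kept their calls in each of these settings. M2 replicate 2 also had reads on 3759 genes that no other library covered, against 160 to 453 in the other 11 libraries.

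**Figure D3:**
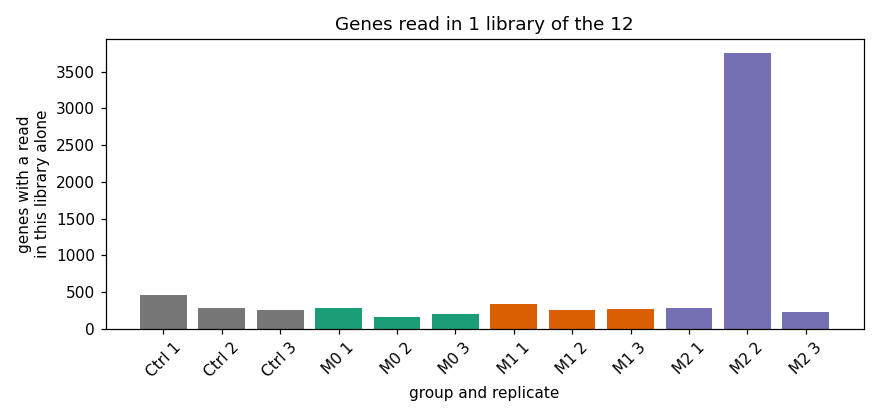
Number of genes with a read in 1 library alone among the 12, as bars from 0, by group and replicate. M2 replicate 2 had 3759 such genes and the other 11 libraries 160 to 453.

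The direct comparison of M1 with M2 tested the difference between both polarized media. CXCL8 was 36.6-fold higher in M1, at 970 ± 147 against 26.4 ± 7.49 CPM (log2 5.19 ± 0.26 SE, adjusted p = 6.92e-08), ICAM1 8.99-fold higher (adjusted p = 2.77e-11) and TNFAIP3 16.4-fold higher (adjusted p = 1.42e-14). IL6 was higher by log2 1.82 ± 0.12. On the other side, TNC was lower in M1 by a log2 fold change of -1.10 ± 0.10 SE (adjusted p = 1.23e-06), at 310 ± 1.65 against 666 ± 78.4 CPM. TENM2 was lower by -3.81 ± 0.30, the keratin gene KRT16 by -3.55 ± 0.27, and ST8SIA1, the GD3 ganglioside synthase gene, by -3.03 ± 0.24. CCL26 had 2 reads in M1 and 76 in M2.

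All 30 type I interferon genes (median log2 4.38, adjusted p = 3.45e-40) and all 16 MHC class I genes (median 1.74, 2.08e-22) were higher in M1 than in M2, with 30 and 16 adjusted over the list alone. Higher too were 21 of 23 NF-kB genes, 21 adjusted over the list alone (median 1.10, 3.31e-19), and 9 of 12 interferon-gamma-type genes, 9 adjusted over the list alone (median 2.01, 7.73e-10). Of 18 cytokine genes 17 were higher and IL11 lower, 17 and 1 adjusted over the list alone (median 2.53, 1.63e-15). These 5 lists also passed with an estimated correlation. Cell cycle genes had 11 of 27 lower and 1 higher, CCNE2, and 14 and 1 adjusted over the list alone (median -0.32, adjusted p = 0.00058, but adjusted p = 0.299 with an estimated correlation). The interleukin 4 and 13 list, with 2 higher and 2 lower, did not pass (adjusted p = 0.968). In all, 4572 genes differed, 2240 higher and 2332 lower in M1, and 682 by at least 2-fold.

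**Figure D4:**
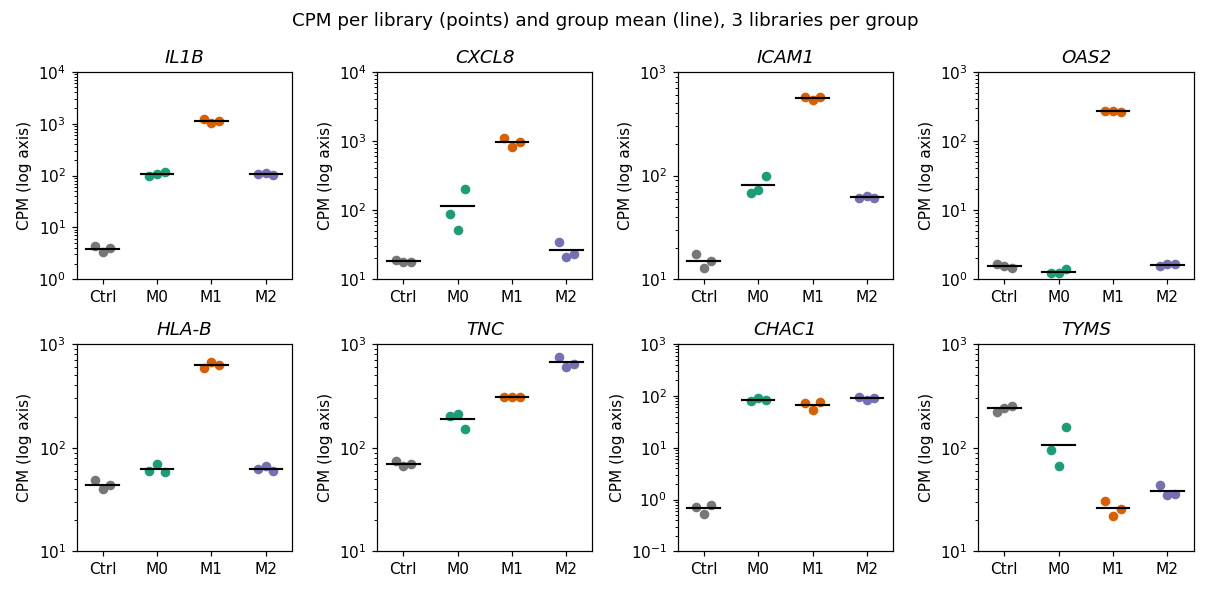
CPM per library (points, log axis) and group mean (line) of 8 genes in Ctrl, M0, M1 and M2, with 3 libraries per group. IL1B is at 108 ± 10.2 CPM in M0 and 1120 ± 95.2 in M1, and CHAC1 at 0.675 ± 0.126 in Ctrl and 84.8 ± 4.68 in M0.

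Amino acid response genes governed by the transcription factor ATF4 rose in M0 medium against fresh medium. CHAC1, a glutathione-degrading enzyme gene, rose 124-fold, from 0.675 ± 0.126 to 84.8 ± 4.68 CPM (log2 6.95 ± 0.16 SE, adjusted p = 4.95e-14), and SESN2, a stress-induced mTORC1 inhibitor gene, rose 72.3-fold to 413 ± 18 CPM (adjusted p = 7.49e-16). Of 18 list members 17 rose, 17 adjusted over the list alone (median log2 3.10, adjusted p = 8.23e-14), and ATF5 fell by 0.40. INHBE, an inhibin beta subunit gene, rose 392-fold, from 0.127 ± 0.0531 to 49.9 ± 9.22 CPM (adjusted p = 1.43e-13). RGS4, a regulator of G protein signalling gene, fell from 64.5 ± 6.23 to 1.17 ± 0.277 CPM (log2 -5.76 ± 0.21 SE, adjusted p = 1.33e-13).

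Inflammatory genes were higher in M0 medium than in fresh medium. IL1B rose 27.6-fold, from 3.89 ± 0.444 to 108 ± 10.2 CPM, and IL6 16.9-fold, from 2.76 ± 0.331 to 45.9 ± 5.42 CPM. CXCL8 rose by log2 2.66 ± 0.59 (adjusted p = 1.22e-05), or 1.92 without M0 replicate 3. Of 18 cytokine genes 14 rose and CXCL1 fell, 15 and 1 adjusted over the list alone (median log2 2.01, or 1.65 with the gene near 0 reads at its bound, adjusted p = 3.85e-05, but adjusted p = 0.282 with an estimated correlation). Of 23 NF-kB genes 19 rose, among them RELB at log2 3.00 ± 0.09, and CD83 fell, 19 and 1 adjusted over the list alone (median 1.08, adjusted p = 7.65e-07, but adjusted p = 0.282 with an estimated correlation). Type I interferon genes had 6 of 30 up and 9 down, 6 and 9 adjusted over the list alone, and did not pass (adjusted p = 0.764).

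Proliferation and sterol genes were lower in M0 than in Ctrl. Of 27 cell cycle genes 22 fell, 22 adjusted over the list alone (median log2 -0.79, adjusted p = 4.25e-06, but adjusted p = 0.282 with an estimated correlation), with CDC20 at -1.58 ± 0.25 SE and the replication helicase gene MCM3 at -1.56 ± 0.14. Of 19 cholesterol synthesis genes 14 fell and 2 rose (SC5D and SREBF2), 14 and 2 adjusted over the list alone (median -0.67, adjusted p = 0.00213, but adjusted p = 0.38 with an estimated correlation). Of 13 NRF2 and metallothionein genes 12 rose, 13 adjusted over the list alone (median 0.71, adjusted p = 0.000139, but adjusted p = 0.282 with an estimated correlation), with the thioredoxin reductase gene TXNRD1 rising from 448 ± 12.4 to 1940 ± 120 CPM. Of 16 MAPK output genes 10 rose and 2 fell (DUSP4 and JUN), 10 and 2 adjusted over the list alone (median 0.75, adjusted p = 0.00328, but adjusted p = 0.282 with an estimated correlation). MITF, the melanocyte lineage factor gene, rose from 1.17 ± 0.387 to 3.10 ± 0.182 CPM (log2 1.38 ± 0.29 SE, adjusted p = 3.24e-05). In all, 8695 genes differed between M0 and Ctrl, 4386 higher and 4309 lower, and 2309 by at least 2-fold.

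Both polarized media were also compared with fresh medium. The ATF4 list rose in both, with 17 of 18 up in M1 (median log2 3.15, adjusted p = 1.13e-11) and 17 of 18 up in M2 with ATF5 down (median 3.14, adjusted p = 2.05e-12), 17 each adjusted over the list alone. SESN2 rose by log2 5.85 ± 0.14 in M1 and 6.18 ± 0.13 in M2, and INHBE by 9.67 ± 0.23 in M2. RGS4 fell by 8.27 and 6.38 on the log2 scale. All 27 cell cycle genes fell in M1 (median -1.58, adjusted p = 2.19e-10, but adjusted p = 0.0773 with an estimated correlation) and 26 in M2 (median -1.42, adjusted p = 3.84e-09, but adjusted p = 0.283 with an estimated correlation), 27 and 26 adjusted over the list alone. TYMS fell by 3.20 in M1 and by 2.65 in M2.

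In M1 against Ctrl, IL6 rose 92.7-fold, from 2.76 ± 0.331 to 253 ± 30.1 CPM (adjusted p = 4.09e-15), ICAM1 36.7-fold and SOD2 30.7-fold. All 30 type I interferon genes (median log2 4.38, adjusted p = 7.96e-16), all 23 NF-kB genes (2.36, 1.13e-11) and all 16 MHC class I genes (1.85, 7.37e-09) rose, with 30, 23 and 16 adjusted over the list alone. CSF2, the GM-CSF gene, had 577 reads in M1 and 0 in Ctrl, at least 189-fold higher. In M2 against Ctrl, TNC rose 9.5-fold (log2 3.25 ± 0.11 SE, adjusted p = 2.92e-12) and IL6 26.3-fold, while CXCL8, at 26.4 ± 7.49 against 18.1 ± 0.667 CPM, did not pass (adjusted p = 0.191) but passed in 3 other settings (0.0148 to 3.23e-10). Of 23 NF-kB genes 19 rose in M2 and CD83 fell, 19 and 2 adjusted over the list alone (median 0.87, adjusted p = 4.69e-05, but adjusted p = 0.283 with an estimated correlation). The genes that differed from Ctrl numbered 9892 in M1, 4961 higher and 4931 lower, and 9370 in M2, 4805 higher and 4565 lower.

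The tumour necrosis factor axis named in the study's title was followed through a fixed panel. Its values are RNA of the melanoma cells, so they do not measure TNF protein in the media. Nor do RNA levels of NFKB1 and RELA measure activity of the NF-kB pathway. TNF itself had 1, 1, 4 and 1 reads in all libraries of Ctrl, M0, M1 and M2, TNFRSF1B 0, 1, 1 and 0, and CCL2 1, 1, 19 and 7, so all 3 stayed below the filter. TNFRSF1A, the main TNF receptor gene, was at 159 ± 17.6, 141 ± 7.85, 118 ± 6.13 and 131 ± 3.16 CPM in Ctrl, M0, M1 and M2. It fell by 0.26 on the log2 scale in M1 against M0 (adjusted p = 0.00979, but 0.0591 without M0 replicate 3) and did not pass in M2 against M0 (log2 -0.11, adjusted p = 0.313) or M1 against M2 (-0.15, 0.142). In M0 against Ctrl it did not pass, but a fall passed in some other settings. Among them were DESeq2 size factors (log2 -0.196, adjusted p = 0.0339) and leaving out M0 replicate 3 (-0.232, 0.028). NFKB1 rose by log2 0.33 ± 0.11 in M1 against M0 (adjusted p = 0.00312) and by 1.08 ± 0.12 in M0 against Ctrl. It fell by 0.40 ± 0.11 in M2 against M0 (adjusted p = 0.0035, but 0.0738 without M0 replicate 3 and M2 replicate 2). RELA, which encodes the p65 subunit, rose by 0.91 ± 0.06 in M0 against Ctrl and differed by 0.01 ± 0.05 between M1 and M2 (adjusted p = 0.959). In M1 against M0 it fell by 0.16 (adjusted p = 0.0362), a call that ended in 10 other settings (0.0504 to 0.247), among them without M0 replicate 2 or 3 (0.106 and 0.219) and without M1 replicate 1 or 2 (0.116 and 0.136). In M2 against M0 RELA did not pass, but a fall passed in some other settings. Among them were a replicate block (log2 -0.166, adjusted p = 0.0469) and leaving out M0 replicate 1 (-0.205, 0.049).

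Markers of the macrophages whose medium was used were near 0 in every group. All 22 lay below the filter, and their summed level was 1.0, 0.8, 0.85 and 0.68 CPM in Ctrl, M0, M1 and M2. CD68, a lysosomal glycoprotein gene of macrophages, was at 0.247 ± 0.067 CPM in Ctrl and 0.204 ± 0.0132 CPM in M1. LYZ, the lysozyme gene, had 0, 3, 3 and 1 reads in Ctrl, M0, M1 and M2.

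Calls shared between comparisons were counted beside what independent lists and simulated shared reference libraries give. Against M0, 1270 genes were higher in both M1 and M2 and 1373 lower in both, where independent lists give 449 and 478. Another 90 genes rose in M1 and fell in M2, and 46 did the opposite. These counts depend on M0 replicate 3, a library of the shared reference. Without it M2 against M0 called 1595 genes in all, fewer than the shared calls above together. The overlap was not recounted without that library. Across genes, which are not independent replicates, the fold changes had a covariance of 0.159, and 100 simulations of unchanged groups gave 0.0176. There all libraries, the M0 ones included, were redrawn around the M0 means, each gene by itself. A deviation that many genes share in a real M0 library, such as replicate 3, could thus not enter them. The correlation was 0.519, no higher than the 0.528 of those simulations, so by itself it gives no evidence of a shared response. Those simulations called 0 genes in both on average, as no gene was changed in them. Against Ctrl, M1 and M2 shared 3947 higher and 3823 lower genes, where independent lists give 1692 and 1598. The covariance was 1.04 beside a simulated 0.0157, from libraries redrawn in the same way around the Ctrl means. With 3 reference libraries the controls could not be halved, so part of the excess may come from the shared controls.

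Key genes lay at these GRCh38 positions in the annotation. OAS2 (ENSG00000111335.12) spans chromosome 12 from 112978395 to 113011723, TNFAIP3 (ENSG00000118503.14) chromosome 6 from 137867188 to 137883312, and HLA-B (ENSG00000234745.10) chromosome 6 from 31269491 to 31357188. ICAM1 (ENSG00000090339.8) spans chromosome 19 from 10270835 to 10286615, IL6 (ENSG00000136244.11) chromosome 7 from 22725884 to 22732002, and CXCL8 (ENSG00000169429.10) chromosome 4 from 73740506 to 73743716. TYMS (ENSG00000176890.15) spans chromosome 18 from 657604 to 673578, TNC (ENSG00000041982.15) chromosome 9 from 115019578 to 115118257, and CCL26 (ENSG00000006606.8) chromosome 7 from 75769533 to 75789896. CHAC1 (ENSG00000128965.11) spans chromosome 15 from 40952962 to 40956519, SESN2 (ENSG00000130766.4) chromosome 1 from 28259527 to 28282491, and INHBE (ENSG00000139269.2) chromosome 12 from 57452323 to 57459280. Counts cover whole genes, so no value refers to a single exon or untranslated region.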

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

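The tests of greater depth, of RNA from another cell type, of weaker exposure, of carried-over macrophage RNA, of scaling and of library depth were chosen after the result was seen. The scaling test is the third form tried, after 2 on the median of all genes, which the scaling itself holds near 0, and the depth test replaced a planned one that decided nothing. Other splits of the same libraries were counted for each number of changed genes. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and in each the real split alone, 1 of 10, called as many genes. The real values were 7354 for M1 against M0, 3553 for M2 against M0, 4572 for M1 against M2, and 8695, 9892 and 9370 for M0, M1 and M2 against Ctrl. The highest other split called 1 gene for M2 against M0 and 0 in the other 5. For any difference among M0, M1 and M2, 1 of 100 splits, the real one, gave as many genes, 7970 against at most 3463 in the others. Chance assignment of these libraries can thus be excluded as the whole of that count. A chance difference between cultures or batches of medium cannot, since the replicates may not be separate cultures.

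Of the 136 genes whose change against M0 passed in opposite directions in M1 and M2, 16 were among the genes named by the rule. Genes higher with M1 medium and lower with M2 medium, by the log2 difference of M1 from M2, were CXCL8 (5.19), TNFAIP3 (4.04), GBP2 (3.88), PSMB9 (3.64), TRAF1 (3.58), SOD2 (3.57), BIRC3 (3.29), ICAM1 (3.17), PSMB8 (2.37), TNFRSF9 (2.09), STARD4 (1.14) and NFKB1 (0.73). Genes lower with M1 and higher with M2 medium were TENM2 (-3.81), KRT16 (-3.55), ST8SIA1 (-3.03) and UHRF1 (-0.74). The opposite calls against M0 held for 12 of the 16 without M0 replicate 3, 13 without M2 replicate 2, 12 without M2 replicate 3 and 7 without both M0 replicate 3 and M2 replicate 2. Those 7 were BIRC3, CXCL8, GBP2, KRT16, ST8SIA1, TENM2 and TNFAIP3.

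IL1B, IL6, CXCL8 and ICAM1 were far higher in M1 than in the other groups. RNA carried over from macrophages is argued against, since the 22 marker genes summed to 0.076% of the IL1B level in M1. Scaling of the M1 libraries is argued against as the whole cause, since the lowest log2 difference of the 4 genes from M0 was 2.45 ± 0.15 SE with library totals alone, and the TMM factors were 0.96 to 0.985 in M1 and 0.973 to 0.99 in M0. A response of the melanoma cells to M1 medium, which the design names, stays open and untested. So does lipopolysaccharide or interferon-gamma left in that medium, which was not measured.

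M2 replicate 2 had reads on 3759 genes silent in the other 11 libraries, and 862.2 CPM in all on genes below the filter, above the 549.6 to 664.9 of the Ctrl libraries. Greater depth is argued against, since with all libraries thinned to the smallest total it still had 9.88 times as many genes read in it alone as the next library, 3359 against 340. RNA of another cell type is argued against, since the reads fell on 96.3% of the number of genes expected if they were spread by exonic length. A trace of genomic DNA may be the source, since reads per exonic kb of protein-coding, lincRNA and processed pseudogene classes lay within 1.23-fold of each other, at 0.147, 0.182 and 0.18, against 2.16 to 6.12-fold in the other 11 libraries. Those other ratios rest on 108 to 312 reads, against 3561 in M2 replicate 2, so part of their spread may be counting noise. Outside that range in M2 replicate 2 were antisense genes at 0.188 and unprocessed pseudogenes at 0.121 reads per exonic kb. No biological explanation was tested.

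M0 replicate 3 stood apart from M0 replicates 1 and 2 on component 3. A swap of labels with a library of another group is argued against, since 0 libraries lay nearer, by root mean square distance, to another group than to the rest of their own. The plan had named correlation, and distance was used in its place. Weaker exposure to conditioned medium could not be decided, since the correlation across genes of its deviation with the axis from M1 and M2 toward Ctrl was 0.325, between the bounds of 0.2 and 0.5, while M0 replicate 2 deviated about as far (root mean square 0.336 against 0.34) with a correlation of -0.286. Library depth is argued against, since its total was 0.98 times that of replicate 1 and lay between those of the other M0 libraries, while the planned thinning decided nothing (its distance to them was 1.13 times theirs before and 1.15 after, within the bound of 1.2 at the start). A biological difference between samples of the same group was not tested.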

How the results depend on the processing

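Leaving out M0 replicate 3 with M2 replicate 2 and testing protein-coding genes alone were chosen after the result was seen. No value reversed. Of 4068 values of named genes under the alternatives 3971 kept their side of the threshold, 64 no longer passed and 33 newly passed, and of 570 list values 506, 39 and 25 did. Called genes between M2 and M0 ranged from 1595 (without M0 replicate 3) to 3906 (without M0 replicate 2) with single libraries left out, with 1933 without M2 replicate 2 and 1905 without M2 replicate 3, and those changed at least 2-fold from 133 to 447. With both M0 replicate 3 and M2 replicate 2 left out they were 520 and 73, and 2 lists in M1 against M0 no longer passed, interleukin 4 and 13 response and MAPK output (both 0.0635). M0 replicate 3 lies farthest from M2 on component 3, so leaving it out shrinks that difference by construction. In the other comparisons the counts with single libraries left out were 6252 to 7083 for M1 against M0, 3341 to 4135 for M1 against M2, 7891 to 8366, 9400 to 9795 and 8659 to 9142 for M0, M1 and M2 against Ctrl, and 6757 to 7913 for the joint test. Depth limits the genes at a few reads, where a fold change is a ratio with a wide interval or a bound.

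With all libraries kept, counts of genes changed at least 2-fold moved by over 1.5 times under 2 of the settings. With at least 1 CPM in 6 libraries, which leaves fewer genes to test, they were 816 for M1 against M0, 143 for M2 against M0 and 420 for M1 against M2. On the deposited log2 values, whose transformation shrinks changes of low genes, they were 806, 96 and, for M0 against Ctrl, 1510. Upper-quartile scaling moved the share of higher calls between M2 and M0 from 49.7% to 56.2%.

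Replicate numbers were not taken to pair the samples, since no label says so and not every same-numbered pair passed a correlation of 0.1. The 18 correlations of same-numbered samples ran from -0.077 to 0.154, with 6 over 0.1, and a sample correlated best with its own number in 22 of 36 cases, where 12 would be so by chance, so a weak pairing is not excluded. With a replicate block the counts were 7453 for M1 against M0, 3714 for M2 against M0, 4752 for M1 against M2, 8741, 9943 and 9439 for M0, M1 and M2 against Ctrl, and 8069 for the joint test. The block let the dedifferentiated (0.0439) and ATF4 (0.0443) lists pass in M1 against M2 and ended MAPK output (0.0558) in M1 against Ctrl. It also ended the call of AXL and gave one to ID1 and RELA in M2 against M0, and changed no other call among the named genes and lists. Over all genes it kept 7249 of the 7354 calls in M1 against M0 and 3434 of the 3553 in M2 against M0.

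With an estimated correlation, where genes of a list that vary together count as fewer, these lists no longer passed, by adjusted p. Correlation was not the whole reason. The ATF4 list had an estimate of 0.006, under the preset 0.01, and its camera adjusted p in M0 against Ctrl still rose from 8.23e-14 to 0.000781. In M1 against M0 the lists that no longer passed were cytokines 0.0807, interleukin 4 and 13 response 0.216, matrix 0.31, adhesion 0.309, receptors 0.121, cell cycle 0.121, unfolded protein response 0.195 and MAPK output 0.31. In M2 against M0 they were interleukin 4 and 13 response 0.198 and cell cycle 0.528. In M1 against M2 they were matrix 0.299, adhesion 0.169, receptors 0.0941, cell cycle 0.299, cholesterol 0.373 and unfolded protein response 0.131. In M0 against Ctrl they were NF-kB, cytokines, cell cycle, NRF2 and MAPK output, each 0.282, and cholesterol 0.38. In M1 against Ctrl they were cytokines 0.0773, cell cycle 0.0773, matrix 0.487, receptors 0.219, NRF2 0.219, cholesterol 0.497, unfolded protein response 0.359 and MAPK output 0.373. In M2 against Ctrl they were NF-kB, cell cycle and NRF2, each 0.283, and cytokines, cholesterol and MAPK output, each 0.397.

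With fry, which asks whether a list's genes move on balance and not whether they exceed other genes, further lists passed. In M1 against M0 they were dedifferentiated state 0.00122, ATF4 0.000215 and TGF-beta and YAP 0.0134, and in M1 against M2 melanocytic 0.0205, dedifferentiated state 0.00226, ATF4 0.00051 and MAPK output 0.00635. In M0 against Ctrl they were interferon-gamma-type 3.79e-06, MHC class I 0.0026, dedifferentiated state 0.00325, matrix 0.00404, receptors 0.000158 and unfolded protein response 9.62e-06. In M1 against Ctrl they were interleukin 4 and 13 response 0.000164, adhesion 0.000209 and TGF-beta and YAP 0.000992. In M2 against Ctrl they were interferon-gamma-type 1.01e-06, interleukin 4 and 13 response 0.000105, dedifferentiated state 0.00626, matrix 0.00151, receptors 9.21e-05, unfolded protein response 8.73e-06 and TGF-beta and YAP 0.00289.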

Other observations

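The groups and genes of this part were chosen after their values were seen. Neither group below was tested for enrichment. Of 26 complement components and regulators, part of innate immunity, 9 were measured, and 6 rose in M1 against M0, 0 fell and 3 (C5, CD55 and CD59) did not pass. C1S, a protease of the classical pathway, rose from 1.23 ± 0.166 to 102 ± 13.1 CPM (log2 6.35 ± 0.15 SE, adjusted p = 7.8e-13), C1R from 5.83 ± 0.514 to 50.1 ± 1.91 CPM, and the central component gene C3 from 1.23 ± 0.256 to 14.3 ± 3.23 CPM, each with n = 3 per group. In M2 against M0 0 rose and 2 fell, C5 and CD59, and 7 of the 9 were higher in M1 than in M2 in the direct test.

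Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs, 14 rose against Ctrl in M0, in M1 and in M2, 4, 6 and 4 fell, and 2, 0 and 2 did not pass, with median log2 fold changes of 0.90, 0.74 and 0.79. In M0 against Ctrl GARS rose from 338 ± 3.78 to 1925 ± 69.8 CPM (log2 2.51 ± 0.03 SE, adjusted p = 1.85e-14) and AARS from 232 ± 16 to 1180 ± 36.8 CPM, while QARS fell by 0.42 on the log2 scale. Against M0, 13 of the 20 were lower in M1 and WARS, which is also an interferon-gamma-induced gene, was higher, from 1470 ± 258 to 2747 ± 219 CPM (adjusted p = 4.32e-06). In M2 against M0 10 were lower, 0 higher and 10 did not pass, and in M1 against M2 4 were lower, 1 higher and 15 did not pass.

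Some interferon-gamma-type genes stayed below the filter. Reads summed over Ctrl, M0, M1 and M2 were 0, 0, 32 and 2 for CXCL10, 0, 2, 35 and 1 for CXCL11, 0, 0, 15 and 1 for IDO1, and 0, 0, 11 and 1 for CXCL9. CIITA, the regulator of MHC class II genes, had 4, 2, 8 and 20 reads and HLA-DRA 0, 0, 0 and 2. Counts on the 37 mitochondrial genes were 32.27 to 53.26 CPM in all in 11 libraries and 356.77 CPM in Ctrl replicate 1.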
